A study of Homo sapiens with 12 samples.

How the data were processed

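The samples were 12 arrays of total RNA from K562 cells, 4 each for nilotinib, imatinib and DMSO, assigned to groups by their titles, and 0 columns of the table were left unmapped. Per the labels, the RNA was labelled with biotin and hybridized to Affymetrix U133 A 2.0 arrays. The deposited values are intensity signals on a linear scale, made by the authors with MAS5, per the submitters' processing notes, in a version not given in the sources used here. The mean of each array between its 2% tails was close to 500 (mean over arrays 499.9), so the arrays had been scaled to a common level before deposit. Because these trimmed means lay within 10% of each other, the values were used as deposited, by a rule fixed before the data were examined. MAS5 scales each array by 1 factor and subtracts a local background, so a difference in background or in total RNA composition between arrays stays in the values of dim probe sets.

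Values were taken as log2(signal + 16). Of 22277 probe sets, 62 control probe sets were left out of the fit, and 22215 remained. Probe sets were matched to genes through the annotation table given, with symbols updated by gene identifier. Of them 19064 named 1 gene, 1043 named several and 2108 named none, and the last 2 kinds were left out of the tests. Probe sets with a mean log2 value below the 40th percentile of all probe sets were dropped, and of several probe sets of a gene the one with the highest mean was kept, which left 8021 genes. Detection calls were not used here. No genome positions are given, since the array annotation names no build.

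Genes were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, a variance trend on intensity and moderated tests with 9 residual degrees of freedom before moderation. P-values were adjusted by Benjamini and Hochberg within each of the 3 comparisons, and a gene was called at an adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, with an estimated correlation and fry beside it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Comparisons of single array measures used two-sided exact permutation tests, in which 4 arrays against 4 cannot give a p below 0.0286.

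The 30 lists and the rule for named genes were chosen before the data were examined. The lists were ERK feedback and immediate early genes, STAT5 targets, FOXO targets, MYC targets and ribosome biogenesis, glycolysis, cholesterol synthesis, ATF4 and the amino acid response, DNA replication, mitosis, cell cycle inhibitors, hemoglobins and erythroid membrane proteins, heme synthesis, erythroid and stem cell regulators, markers of megakaryocytes, granulocytes and monocytes, lymphocytes and fibroblasts, the BCL2 family, p53 targets, lysosome and autophagy, the interferon response, BCR, ABL1 and other drug targets, drug transporters, hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, nucleotide synthesis, heat shock, the unfolded protein response and housekeeping genes. The rule named up to 10 genes per direction with the largest change among called genes whose groups did not overlap, up to 4 called members of each list that passed against DMSO, and 18 genes chosen from knowledge of the pathway. Of these 18, DUSP6 lay below the filter, HBG1 and HBA1 had no probe set naming that gene alone, and 1 is not reported here. Added after the values were seen were the differences between the drugs for the list members named against DMSO and the 8 genes called in opposite directions.

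Data were simulated with the real means and spreads for 8021 genes, of which 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. The recovered shares were 34.3%, 83.6% and 97.0% for imatinib against DMSO, 55.2%, 77.6% and 98.5% for nilotinib against DMSO, and 44.8%, 74.6% and 97.0% for nilotinib against imatinib. Each comparison was drawn once with the same spread, so these shares do not compare power between the drugs. Far fewer genes were changed than were called in the real data, so they are not the sensitivity there. Of unchanged genes 0.0895%, 0.102% and 0.102% were called. In a separate draw without changed genes, camera called 0 of 30 lists for imatinib against DMSO, and it found a list then shifted by 0.5. Genes were drawn independently of each other, so this does not test the preset correlation on lists whose genes vary together.

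The alternatives tried, 1 choice at a time, were pseudocounts of 1 and 64, no filter and the 60th percentile, quantile normalization, median centring and cyclic loess, other treatments of several probe sets of a gene, other variance models, array weights, only the 2 groups compared, a minimum log2 change of 1, an estimated correlation in camera, and each array left out in turn. For genes and lists, testing all probe sets separately was defined as the mean of a gene's probe sets, so that alternative and the mean of the probe sets are the same calculation and differ only for counts and the correlation of the drugs. Alternatives chosen after seeing the data were to leave out the 4 arrays of high actin ratio, to use that ratio as a covariate or as a block, and to fit within each array set. No paired analysis was possible because the labels' numbers are not shared between groups.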

Results

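RNA from K562, a human cell line derived from a chronic myeloid leukaemia and carrying the BCR-ABL1 fusion kinase, was measured on 12 Affymetrix U133 A 2.0 arrays. The cells were treated for 24 h with 0.05 µM nilotinib (4 arrays), 0.5 µM imatinib (4 arrays) or the solvent DMSO (4 arrays). Nilotinib, also known as AMN107, and imatinib, also known as STI571, are related small-molecule inhibitors of the ABL kinase. The doses differed, and the labels describe each as the half-maximal inhibitory concentration of its drug. After a filter on low values, 8021 genes were tested. The labels do not say that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of each value, with a median standard error of 0.146 for a log2 fold change. All log2 fold changes are differences of log2(signal + 16), which understates changes of genes with low signal.

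The arrays of the 3 groups differed in more than the genes. The median signal of an array was 119 ± 2.17 with DMSO, 142 ± 8.71 with imatinib and 179 ± 12.1 with nilotinib (SD, n = 4 each). The control probe sets for bacterial transcripts had a median signal of 7.06 ± 1.31, 12.2 ± 4.54 and 18.2 ± 5.35 in the same order, and the 28S ribosomal RNA control had 5431 ± 135, 20453 ± 1241 and 24015 ± 2137 (SD, n = 4 each). Pearson's r across the 8021 genes tested, between arrays of a group, was 0.976 to 0.981 with DMSO, 0.968 to 0.972 with imatinib and 0.941 to 0.961 with nilotinib. No pair of arrays within a group held identical values. The 3'/5' signal ratio of the actin control was above 3.5 on 4 arrays, nilotinib replicates 1 and 2 and imatinib replicates 5 and 6.

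**Figure D1:**
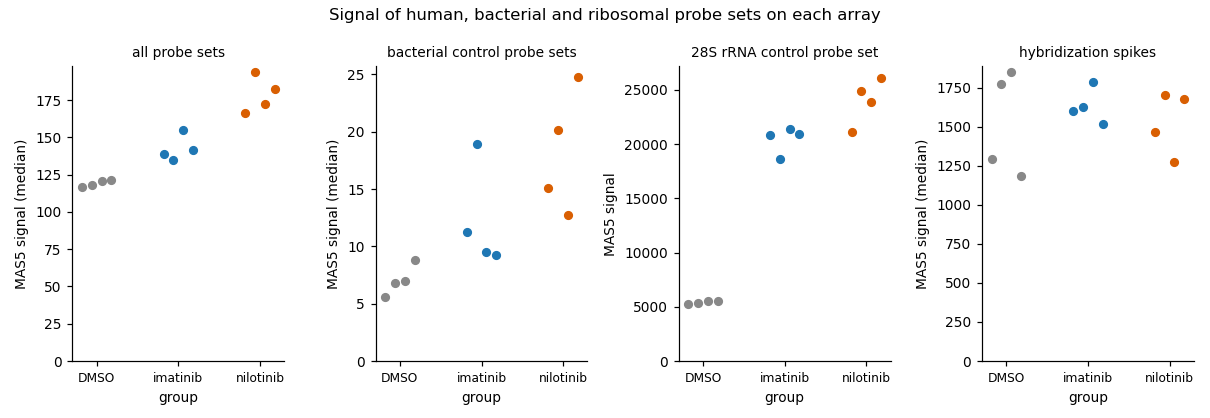
MAS5 signal of each array (vertical axes, starting at 0) by group (horizontal axes), as the median over all probe sets, over the bacterial control probe sets and over the hybridization spikes, and for the 28S rRNA control; each point is 1 array. The median of all probe sets lay at 117 to 121 with DMSO, 135 to 155 with imatinib and 166 to 194 with nilotinib.

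The comparison of imatinib with DMSO asks which transcripts change when the ABL kinase is inhibited in these cells. Red cell genes rose and genes downstream of growth signals fell. ALAS2, which encodes the erythroid enzyme of the first step of heme synthesis, rose from a signal of 232 ± 53.8 to 5299 ± 835 (SD, n = 4 each), a log2 fold change of 4.43 ± 0.13 (SE). TXNIP, an inhibitor of thioredoxin, rose by 4.38 ± 0.08 and HBD, the delta globin gene, by 3.39 ± 0.09 on the log2 scale. CD69, an early activation antigen, had a log2 fold change of -4.50 ± 0.21, and EGR1, an immediate early transcription factor downstream of ERK, of -3.78 ± 0.14. These 5 genes had no overlap between the groups' arrays.

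Of the 12 measured members of the list of hemoglobins and erythroid membrane proteins, 11 rose, none fell and 1 did not pass, with a median log2 fold change of 2.10 (camera adjusted p = 1.55e-13). The chaperone of free alpha globin, AHSP, rose by 3.01 ± 0.20 and the blood group gene KEL by 2.93 ± 0.12. The probe set of HBB (3.36 ± 0.11) is of the kind that can bind related transcripts, so its value cannot be assigned to one globin with certainty. In the list of heme synthesis and iron handling, 13 of 16 members rose and 1 fell (median 0.79, adjusted p = 3.27e-09), among them the mitochondrial iron importer SLC25A37 (2.69 ± 0.11) and PPOX (1.87 ± 0.09). The list of FOXO targets had 10 of 16 members higher and none lower (median 0.49, adjusted p = 5.20e-04, but adjusted p = 0.0930 with an estimated correlation), with CAT, which encodes catalase, at 1.53 ± 0.06 and CITED2 at 1.15 ± 0.07. For lysosome and autophagy, 13 of 24 members rose and 3 fell (median 0.27, adjusted p = 0.0469, but adjusted p = 0.229 with an estimated correlation), and among the drug transporters 3 of 6 rose and none fell (median 0.45, adjusted p = 0.0469, but adjusted p = 0.107 with an estimated correlation). The cathepsin CTSL rose by 1.79 ± 0.07 and the efflux transporter ABCG2 by 1.00 ± 0.11. Both of these calls lie close to the threshold. The lysosome list passed under 20 of 28 alternatives (largest adjusted p = 0.0924, with median centring) and the drug transporters under 19 of 28 (largest adjusted p = 0.0689, without the 4 arrays of high actin ratio).

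Genes of the amino acid response fell together. Of 26 measured members of the ATF4 list, 25 fell and 1 did not pass (median -1.66, adjusted p = 9.04e-28), including TRIB3 (-3.31 ± 0.12), DDIT4 (-3.09 ± 0.10), the tryptophanyl-tRNA synthetase WARS1 (-2.84 ± 0.09) and the asparagine synthetase ASNS (-2.59 ± 0.08). Of 10 STAT5 targets 9 fell (median -1.48, adjusted p = 3.27e-09), with the kinase PIM1 at -2.59 ± 0.14 and the cytokine signalling inhibitor SOCS2 at -2.02 ± 0.07. Of 13 ERK feedback and immediate early genes 9 fell (median -0.93, adjusted p = 1.93e-06), with ETV5 at -2.62 ± 0.28 and SPRY2 at -0.93 ± 0.15. MYC and its targets in ribosome biogenesis fell in 14 of 18 cases (median -0.79, adjusted p = 7.90e-09), with MYC itself at -1.25 ± 0.10. In the unfolded protein response 7 of 13 members fell and 1 rose (median -0.71, adjusted p = 5.33e-04), with XBP1 at -1.49 ± 0.12. Glycolysis had 11 of 18 members lower and 3 higher (median -0.34, adjusted p = 0.00126, but adjusted p = 0.107 with an estimated correlation). Its glucose transporters moved in opposite directions, SLC2A3 at -3.55 ± 0.14 and SLC2A1 at 1.33 ± 0.08. Nucleotide synthesis had 10 of 16 members lower and 1 higher (median -0.42, adjusted p = 6.37e-04, but adjusted p = 0.0902 with an estimated correlation), with PFAS at -0.94 ± 0.15.

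Among other genes named before the data were examined, MYB, a progenitor transcription factor, had a log2 fold change of -1.81 ± 0.08, CCND2, which encodes cyclin D2, of -1.83 ± 0.09, and BCL2L1, a survival gene of the BCL2 family, of -0.93 ± 0.12. The probe sets of the last 2 disagreed in size, with 2 of 3 called lower for CCND2 (-2.28 to -0.22) and 1 of 2 for BCL2L1 (-0.93 and -0.32). The proapoptotic gene BCL2L11 had 0.33 ± 0.17 (adjusted p = 0.128) and BCL6 had 0.53 ± 0.28 (adjusted p = 0.144), neither of which passed. ABL1 had 0.34 ± 0.08, a call lost with median centring, and BCR had 0.39 ± 0.13, a call lost with quantile normalization, cyclic loess and median centring. In all, 3157 of 8021 genes (39.4%) passed limma's moderated test at an adjusted p of 0.05, 1767 higher and 1390 lower, of which 365 and 222 changed by at least 1 on the log2 scale. The arrays of the groups did not overlap for 3133 genes (39.1%), against 2.86% by chance. The median of all genes was 0.09, and with median centring it moved to -0.13, with 820 genes higher and 2276 lower.

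The comparison of nilotinib with DMSO asks the same question of the other inhibitor. ALAS2 rose to a signal of 7231 ± 668 (SD, n = 4), a log2 fold change of 4.89 ± 0.13 (SE), and TXNIP by 4.55 ± 0.08. SLC4A1, which encodes the band 3 anion exchanger of the red cell membrane, rose from 150 ± 11.2 to 2389 ± 244 (SD, n = 4 each), by 3.85 ± 0.11 on the log2 scale. CD69 had -4.57 ± 0.21, EGR1 -3.36 ± 0.14 and the fatty acid binding protein gene FABP5 -2.95 ± 0.26. CYP3A5, a drug-metabolising enzyme gene, rose by 4.40 ± 0.12.

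All 12 measured hemoglobin and erythroid membrane genes rose with nilotinib (median 1.97, adjusted p = 3.39e-10), KEL by 3.45 ± 0.12 and AHSP by 3.30 ± 0.20. Heme synthesis and iron handling had 13 of 16 members higher and 1 lower (median 0.76, adjusted p = 5.47e-07), with SLC25A37 at 3.33 ± 0.11 and ALAD at 2.10 ± 0.13. Of 15 erythroid and stem cell regulators 9 rose and 3 fell (median 0.68, adjusted p = 0.0398, but adjusted p = 0.200 with an estimated correlation, and passing under 26 of 28 alternatives), with TAL1 at 1.66 ± 0.07, EPOR, the erythropoietin receptor gene, at 1.69 ± 0.15 and MYB at -2.49 ± 0.08. The FOXO targets had 12 of 16 members higher (median 0.69, adjusted p = 5.58e-04, but adjusted p = 0.0812 with an estimated correlation), and the drug transporters 5 of 6 (median 0.70, adjusted p = 0.0194, but adjusted p = 0.0812 with an estimated correlation), with ABCG2 at 1.45 ± 0.11. Of 9 cell cycle inhibitors 6 rose and none fell (median 0.43, adjusted p = 0.0205, but adjusted p = 0.207 with an estimated correlation), with CDKN1C, a cyclin-dependent kinase inhibitor gene, at 2.20 ± 0.09, and with median centring this median turned to -0.09 and the call was lost (adjusted p = 0.0777).

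The ATF4 list again had 25 of 26 members lower (median -1.74, adjusted p = 1.16e-19), with TRIB3 at -3.18 ± 0.12 and ASNS at -2.89 ± 0.08. STAT5 targets fell in 9 of 10 cases with 1 higher (median -1.68, adjusted p = 5.67e-07), ERK feedback genes in 8 of 13 (median -0.63, adjusted p = 5.58e-04) and genes of the unfolded protein response in 8 of 13 (median -0.50, adjusted p = 1.63e-04), with SOCS2 at -2.44 ± 0.07, SPRY2 at -1.26 ± 0.15 and HSPA5 at -1.13 ± 0.06. MYC and its targets had 14 of 18 members lower and 1 higher (median -0.90, adjusted p = 6.90e-08), with MYC at -1.91 ± 0.10 and ODC1, an enzyme gene of polyamine synthesis, at -1.93 ± 0.08. Nucleotide synthesis had 13 of 16 members lower and 1 higher (median -0.73, adjusted p = 2.20e-05), with PFAS at -1.54 ± 0.15. Glycolysis had 11 of 18 members lower and 4 higher (median -0.53, adjusted p = 5.58e-04, but adjusted p = 0.0812 with an estimated correlation), with HK2, a hexokinase gene, at -2.87 ± 0.21.

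With nilotinib the division genes were lower as well. Of 33 genes of DNA replication 17 fell and 1 rose (median -0.36, adjusted p = 5.58e-04, but adjusted p = 0.0987 with an estimated correlation), with the replication factor genes CDC45 at -0.76 ± 0.08 and RFC4 at -0.67 ± 0.07. Of 31 genes of mitosis 18 fell and 1 rose (median -0.34, adjusted p = 5.52e-05, but adjusted p = 0.143 with an estimated correlation), with the mitotic kinase genes CDK1 at -0.95 ± 0.12 and AURKA at -0.75 ± 0.10, for which 2 of 3 probe sets were called lower (-0.75 to -0.30). MKI67 had -1.16 ± 0.15 by the probe set used, but of its 4 probe sets 2 were called higher and 2 lower (-1.16 to 0.82), so it has no clear direction. Oxidative phosphorylation had 13 of 25 members lower and 1 higher (median -0.16, adjusted p = 0.00163, but adjusted p = 0.0812 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.490) and cyclic loess (adjusted p = 0.438).

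BCL2L11 rose by 0.81 ± 0.17, BCR by 0.45 ± 0.13 and ABL1 by 0.36 ± 0.08, and these 3 calls were lost with median centring, where BCR and ABL1 turned negative. BCL2L1 had -1.22 ± 0.12 by the probe set used and -0.07, not called, by its other one, and BCL6 had 0.20 ± 0.28 (adjusted p = 0.561). In all, 4666 of 8021 genes (58.2%) passed, 2781 higher and 1885 lower, of which 929 and 435 changed by at least 1 on the log2 scale. The arrays did not overlap for 4069 genes (50.7%), against 2.86% by chance. The median of all genes was 0.15, and with median centring it moved to -0.37, with 831 genes higher and 3947 lower, so the balance between higher and lower genes rests on the scaling.

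**Figure D2:**
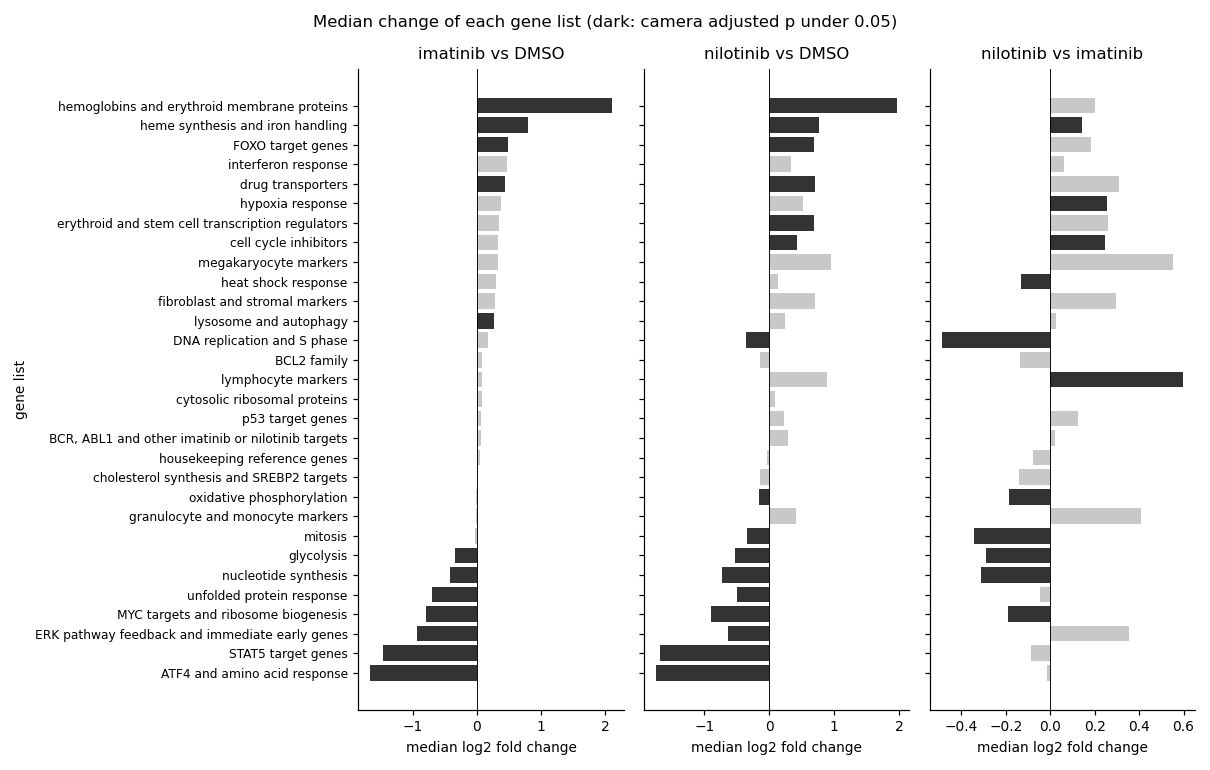
Median log2 fold change (horizontal axes) of each of the 30 gene lists (vertical axis) in the 3 comparisons, with dark bars for lists past camera's adjusted p of 0.05. The hemoglobin list stood highest at 2.10 and 1.97 against DMSO and the ATF4 list lowest at -1.66 and -1.74, and of the lists with dark bars, the cell cycle inhibitors (nilotinib vs DMSO) and the cell cycle inhibitors, heme and hypoxia lists (nilotinib vs imatinib) turned negative with median centring.

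The changes of both drugs against DMSO were compared across genes. Across 8021 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.888 and a Spearman correlation of 0.857. Simulated unchanged groups, sharing 4 simulated DMSO arrays with noise drawn independently per gene, gave a mean Pearson correlation of 0.500, because of shared controls. Their mean covariance was 0.0237 against the observed 0.390, a difference of 0.366. With 2 DMSO arrays for one drug and the other 2 for the other, over 6 splits, the correlation was 0.797 to 0.827 and the covariance 0.367 to 0.376. Both drugs raised 1570 genes, against 612.6 for independent lists, and lowered 1245, against 326.7. Independent lists ignore the shared controls, and the simulated unchanged groups gave at most 1 gene called in the same direction with both drugs. Of the 2823 genes called with both drugs, 8 were called in opposite directions. These 8, named after their values were seen, were DTL, DUT, HELLS, MEA1, NDUFB11, NDUFB2, SNRNP25 and TOP2A, each higher with imatinib and lower with nilotinib by the probe set used (with imatinib 1 of 3 probe sets called for DUT and 1 of 2 for NDUFB2 and TOP2A), and each lost at least 1 of these calls under quantile normalization.

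**Figure D3:**
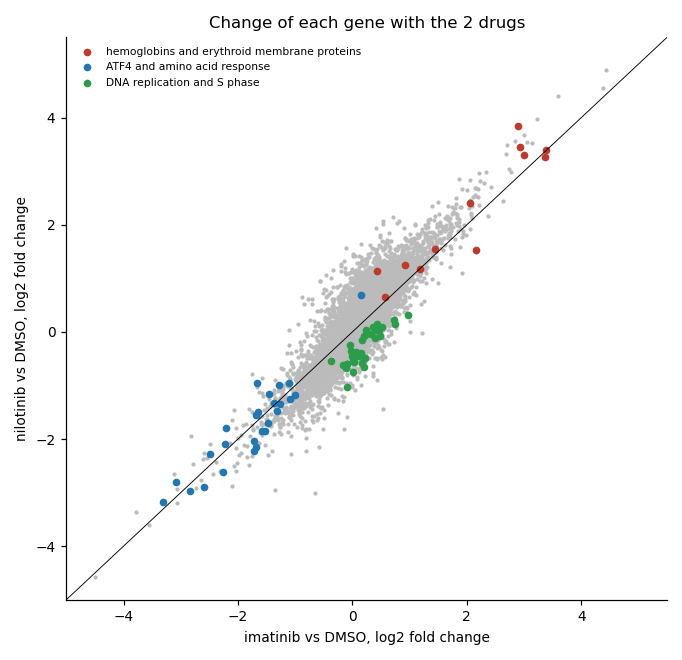
Log2 fold change of each of the 8021 genes with imatinib (horizontal axis) and nilotinib (vertical axis) against DMSO, with 3 gene lists in colour and the line of equal change. Hemoglobin and ATF4 genes lie near the line, and the replication genes lie below it.

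The comparison of nilotinib with imatinib asks whether the related inhibitors, at doses that differed, left the cells in different states. Many genes of DNA replication and cell division were lower with nilotinib. CDC45 had a signal of 2073 ± 172 with imatinib and 1215 ± 121 with nilotinib (SD, n = 4 each), a log2 difference of -0.77 ± 0.08 (SE), GINS1 had -0.87 ± 0.12 and CDK1 had -0.90 ± 0.12. MYC was lower with nilotinib by -0.66 (95% interval -0.86 to -0.46). SLC4A1 was higher with nilotinib by 0.96 ± 0.11.

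Of 33 genes of DNA replication 21 were lower with nilotinib and none higher (median -0.49, adjusted p = 7.90e-22), and of 31 genes of mitosis 15 were lower and none higher (median -0.34, adjusted p = 7.31e-11, but adjusted p = 0.0546 with an estimated correlation). Within the 2 arrays per drug of high actin 3'/5' ratio the medians were -0.50 and -0.32, and within the 2 of lower ratio -0.48 and -0.36. Nucleotide synthesis had 8 of 16 members lower and 1 higher (median -0.31, adjusted p = 7.00e-06), with NME1 at -0.62 ± 0.07. MYC targets had 5 of 18 members lower (median -0.19, adjusted p = 1.26e-04), with ODC1 at -0.86 ± 0.08, and oxidative phosphorylation had 9 of 25 lower (median -0.19, adjusted p = 5.46e-07), with ATP5F1B at -0.22 ± 0.06, a call of that gene lost with quantile normalization and cyclic loess. The list's median shrank to -0.10 with quantile normalization (adjusted p = 0.0222) and to -0.09 with cyclic loess (adjusted p = 0.0447). Glycolysis had 8 of 18 members lower and 2 higher (median -0.29, adjusted p = 0.00647, but adjusted p = 0.171 with an estimated correlation), with HK2 at -0.76 ± 0.21 (1 of 2 probe sets called). The heat shock list had 4 of 10 members lower (median -0.13, adjusted p = 0.00572, but adjusted p = 0.113 with an estimated correlation), a call lost with cyclic loess (adjusted p = 0.0925).

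Other lists were higher with nilotinib, and their calls depended on the correlation assumed. Heme synthesis had 5 of 16 members higher (median 0.14, adjusted p = 0.0161, but adjusted p = 0.196 with an estimated correlation, and passing under 23 of 28 alternatives), with SLC25A37 at 0.64 ± 0.11 and ALAD at 0.75 ± 0.13, and with median centring its median turned to -0.16. The hypoxia list had 2 of 11 higher (median 0.25, adjusted p = 0.0174, but adjusted p = 0.113 with an estimated correlation) and the cell cycle inhibitors 3 of 9 (median 0.25, adjusted p = 0.0461, but adjusted p = 0.251 with an estimated correlation), and with median centring these medians turned to -0.04 and -0.05. These 2 lists passed under 26 and 19 of 28 alternatives. The hemoglobin list (median 0.20, adjusted p = 0.0519) and the erythroid and stem cell regulators (0.26, adjusted p = 0.0535) did not pass, did so with quantile normalization (adjusted p = 0.00468 and 0.00237), and turned to -0.10 and -0.04 with median centring. In turn they passed under 16 and 10 of 28 alternatives. The lymphocyte markers, genes of another cell type, had 2 of 8 higher (median 0.60, adjusted p = 0.0171, but adjusted p = 0.171 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.0513), with cyclic loess (adjusted p = 0.0793) and without a filter (adjusted p = 0.166). On the nilotinib arrays the bacterial control probe sets were higher too, by a log2 difference of 0.28 from imatinib (two-sided exact permutation p = 0.114). Of the genes called between the drugs, 83.2% were higher with nilotinib in the lowest of 3 equal groups of genes by mean signal, 64.7% in the middle one and 21.2% in the highest.

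Where the drugs did not differ by the test, the intervals were as follows. BCR differed by 0.06 (95% interval -0.23 to 0.34), ABL1 by 0.02 (-0.15 to 0.19), HBZ, the zeta globin gene, by 0.00 (-0.15 to 0.15) and HBD by 0.01 (-0.18 to 0.20), and with median centring ABL1, HBZ and HBD were called lower with nilotinib. PIM1 differed by 0.32 (0.03 to 0.61, adjusted p = 0.121), CISH by -0.12 (-0.46 to 0.22) and TRIB3 by 0.13 (-0.12 to 0.39). ALAS2 was higher with nilotinib by 0.46 ± 0.13 and KEL by 0.52 ± 0.12, and both calls were lost with median centring. MYB and TAL1 have no clear direction between the drugs, since their 2 probe sets each gave -0.68 (called) and 0.26 for MYB, and 0.43 (called) and -0.29 for TAL1. SOCS2 was lower with nilotinib by -0.42 with 1 probe set, and by -0.14, not called, with the other. The largest differences by the rule were SAC3D1 at -2.35 ± 0.36 and COMMD9 at -1.96 ± 0.38, and RDH8 at 1.67 ± 0.33 and RAB11B at 1.53 ± 0.34. On every imatinib array RDH8 lay below the filter's log2 level of 6.59, at 5.55 to 6.49. A difference in background between arrays stays in values this low, and its share in the RDH8 difference was not tested. In all, 1126 of 8021 genes (14.0%) passed, 467 higher and 659 lower with nilotinib, and 67 and 20 of these differed by at least 1 on the log2 scale. The arrays did not overlap for 1447 genes (18.04%), against 2.86% by chance. Within the arrays of high actin ratio 654 genes passed and within those of lower ratio 335. Without the 4 arrays of high ratio, an alternative chosen after seeing the data, 414 passed, 107 higher and 307 lower, and without imatinib replicate 6, 694 passed, 248 higher and 446 lower. The higher genes also dropped to 289 without nilotinib replicate 4, to 310 without imatinib replicate 8 and to 302 without nilotinib replicate 2, an array that stood apart from the other nilotinib arrays on the second principal component (30.7 against -2.23 to 4.84). With median centring 76 genes were higher and 2646 lower, and the median of all genes moved from 0.05 to -0.25.

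**Figure D4:**
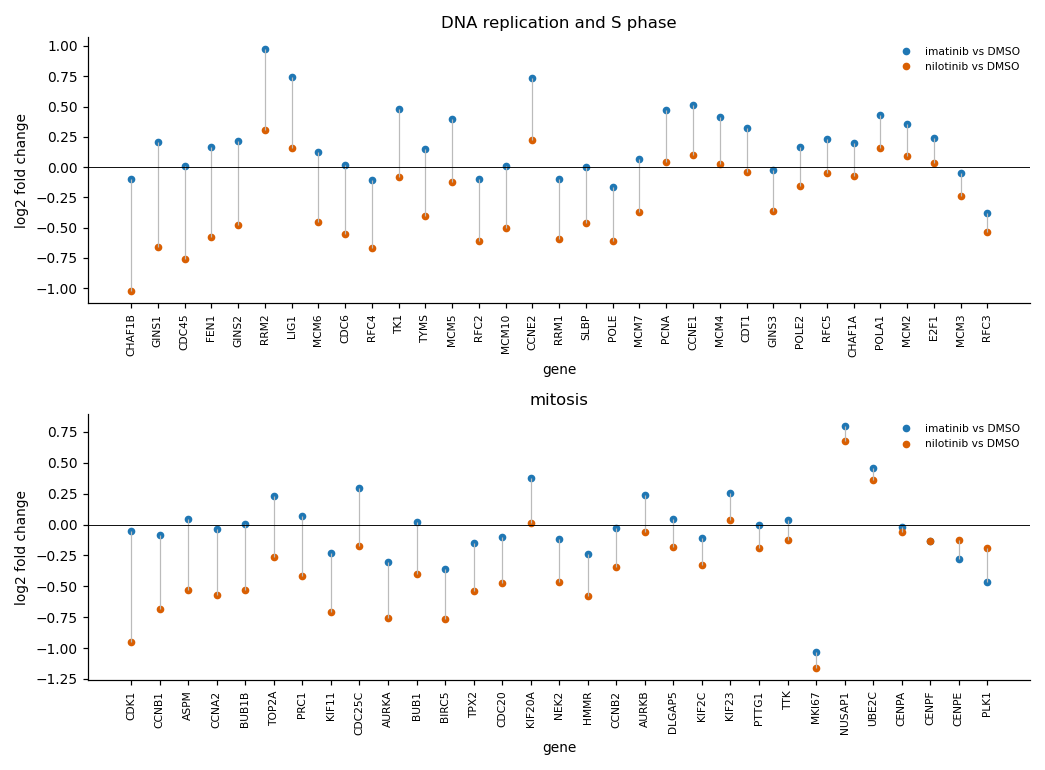
Log2 fold change against DMSO (vertical axes) of each measured gene of the replication and mitosis lists (horizontal axes, ordered by the difference between the drugs), with 1 point per drug and a line joining them. For most genes the nilotinib point lies below the imatinib point, with medians of -0.36 against 0.17 for replication and -0.34 against -0.03 for mitosis, and the imatinib medians changed sign with median centring (replication) and with quantile normalization (mitosis).

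The remaining lists did not pass as deposited, and many of their medians rest on the scaling. Against DMSO, the replication list had a median of 0.17 with imatinib (12 higher, 1 lower of 33, adjusted p = 0.0723) a rise that passed with quantile normalization (adjusted p = 0.00970) and cyclic loess (adjusted p = 0.0229) and turned to -0.06 with median centring. The mitosis list had -0.03 (adjusted p = 0.450), which turned to 0.02 with quantile normalization. With imatinib and nilotinib in turn, the medians were 0.33 and 0.95 for megakaryocyte markers (adjusted p = 0.523 and 0.245), -0.02 and 0.41 for granulocyte and monocyte markers (0.907 and 0.708), 0.28 and 0.71 for fibroblast and stromal markers (0.811 and 0.542), and 0.47 and 0.33 for the interferon response (0.526 and 0.742). They were 0.08 and 0.89 for lymphocyte markers (0.932 and 0.255), 0.37 and 0.52 for hypoxia (0.166 and 0.0758) and 0.29 and 0.13 for heat shock (0.450 and 0.756). With imatinib alone, cell cycle inhibitors had 0.33 (adjusted p = 0.0723), erythroid and stem cell regulators 0.35 (adjusted p = 0.0927) and oxidative phosphorylation -0.01 (adjusted p = 0.526), and with nilotinib alone the lysosome list had 0.24 (adjusted p = 0.0758). The medians were 0.08 and -0.15 for the BCL2 family (0.166 and 0.183), 0.06 and 0.23 for p53 targets (0.758 and 0.960), 0.01 and -0.14 for cholesterol synthesis (0.761 and 0.542), 0.07 and 0.08 for cytosolic ribosomal proteins (0.526 and 0.756), 0.05 and -0.04 for housekeeping genes (0.761 and 0.664), and 0.06 and 0.29 for BCR, ABL1 and other drug targets (0.303 and 0.389). Under at least 1 of the other scalings the median changed sign with imatinib for the cholesterol, lymphocyte, BCL2, p53, drug target, oxidative phosphorylation, ribosomal protein and housekeeping lists. With nilotinib it did so for the granulocyte, p53, lysosome, interferon, hypoxia, heat shock, drug target, ribosomal protein and housekeeping lists. Median centring lowers every log2 fold change of a comparison by the same amount, so positive medians smaller than that amount turn negative by construction. The median differed in sign from the mean or from the test with imatinib for the granulocyte, BCL2, p53 and drug target lists, and with nilotinib for the cholesterol, drug target, heat shock and housekeeping lists. It did so between the drugs for the ATF4, interferon, drug target and ribosomal protein lists. Lists passing in the 3 comparisons numbered 12, 16 and 11, and 7, 8 and 4 with an estimated correlation. Adjusted over the list alone, the replication list had 27 members lower with nilotinib than with imatinib where 21 passed over all genes, the mitosis list 17 where 15 did, and the ATF4 list 25 lower with each drug against DMSO, as over all genes. With nilotinib the remaining ATF4 member was then called higher, which it was not over all genes.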

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

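Values of single arrays far from the others of their group were looked for by Dixon's test among the genes chosen by the rule for named genes and its additions, as log2(signal + 16), and among 8 measures of each array from control probe sets and the median of all probe sets, and signals in data outside the report's tests were looked for among the control probe sets and the probe sets naming no single gene. Of the tests below on patterns, the splits of the arrays, the test of normalization and the test of 5' signal were written before their results were seen, and those of nonspecific signal, of one scaling factor, of a proportionally stronger imatinib response and of globin probe sets were chosen after the deciding values had been seen.

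An array stood apart 18 times in 396 tests, of 124 genes and 8 array measures in each of 3 groups, and each time in a gene, where about 19.8 (1 in 20) arise by chance, so no pattern is read from them. Replicate 2 of nilotinib had the most, with PLAAT4 at 8.39 (the others 8.91 to 8.99), ETV5 at 6.10 (7.52 to 7.57), CCND2 at 9.96 (10.23 to 10.27) and EXOG at 6.97 (5.41 to 5.53). Replicate 4 of nilotinib had MYC at 11.61 (11.48 to 11.49) and EPOR at 9.74 (10.39 to 10.48), and replicate 3 had GAA at 8.42 (7.88 to 7.95). Imatinib replicate 5 had MYB at 10.18 (10.49 to 10.52) and ATP5F1B at 12.92 (13.07 to 13.09), replicate 6 had HBZ at 14.37 (14.56 to 14.59), and replicate 7 had RDH8 at 5.55 (6.43 to 6.49). In DMSO, replicate 10 had SLC2A1 at 10.10 (10.02 to 10.03), EPOR at 8.92 (8.40 to 8.49) and CAMK2A at 4.90 (6.54 to 6.58), replicate 11 had NFASC at 5.10 (6.29 to 6.52) and DHODH at 7.76 (8.05 to 8.08), and replicate 12 had DDX21 at 12.53 (12.62 to 12.64) and GART at 10.26 (10.55 to 10.61).

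Probe sets outside the tests of genes also differed from DMSO. The 18S rRNA control was higher by 1.21 with imatinib and 1.70 with nilotinib on the log2 scale, the 28S rRNA control by 1.91 and 2.14, and the median of the bacterial control probe sets by 0.28 and 0.56. For each of these 6 differences the arrays did not overlap, and the two-sided exact permutation p was 0.0286, the smallest that 4 arrays against 4 can give (0.0444 adjusted over 42 tests of array measures). Among 1633 probe sets naming no single gene, 581 changed with imatinib and 971 with nilotinib. The 3 comparisons were tested against other splits of the same 8 arrays. In each, 1 of 35 splits, the real one, gave as many genes (3157, 4666 and 1126), and the highest other split gave 0, 0 and 13 genes. In the other splits the real differences between the groups widen the spread. Their low counts therefore do not measure how many calls arise by chance.

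Probe sets of low signal were brighter on treated arrays. With nilotinib the median log2 difference from DMSO was 0.53 in the dimmest of 5 equal groups of probe sets. The bacterial control probe sets, whose targets K562 RNA does not contain, rose by 0.56 in the median, so nonspecific signal on the treated arrays remains as an explanation. A single wrong scaling factor per array cannot give this pattern by itself, because the brightest group of probe sets moved by -0.081. All arrays had been scaled to a common trimmed mean, to which bright probe sets contribute most. A factor that offset a fall of bright transcripts is therefore not excluded. An effect of the drugs on the composition of the RNA was not tested and stays open.

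The replication and mitosis lists were lower with nilotinib than with imatinib, though the mitosis call was lost with an estimated correlation (camera adjusted p = 0.0546). Normalization is excluded as the cause for both lists by the test, with a replication mean of -0.46 against other genes under cyclic loess. A difference in 5' signal is excluded for the replication list, whose mean was -0.55 in the array set with the smaller difference. The same list lay -0.57 from the slope of nilotinib on imatinib changes. With an imatinib mean of only 0.20, this value nearly repeats the difference itself (-0.56), which was known when the test was chosen. As deposited, the list's means had opposite signs (0.20 with imatinib, -0.28 with nilotinib), which a response stronger by 1 factor over all genes does not give. The imatinib median turned negative with median centring, however, so such a response is not excluded. A stronger response that is not proportional over genes is not excluded either, and whether the compound or its dose made the difference was not tested and stays open.

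The rise of hemoglobin and red cell membrane genes was tested for probe sets that bind several globins. Without the 5 globin genes the other 7 members had a median log2 fold change of 2.06 with imatinib (6 higher, none lower) and 2.40 with nilotinib (7 higher). Camera called the rise of these members with each drug, so cross-hybridization among globins alone does not account for the list's rise. The outcome could be foreseen, since the test was chosen after these members had been seen to rise. It does not cover the size of the rise of the 5 globin genes. An effect of both drugs on erythroid genes is in line with this test, which does not separate it from other causes.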

How the results depend on the processing

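Alternatives were chosen before the data were examined, except those on the actin ratio. The 3 scalings and the filter move the balance of higher and lower genes, while most named values kept direction and call. For nilotinib vs DMSO the higher genes were 2781 (59.6% of those changed) as reported, 3658 (66.2%) with no filter, 1858 (51.6%) with a filter at the 60th percentile, 1978 (48.8%) with quantile normalization, 2028 (49.4%) with cyclic loess and 831 (17.4%) with median centring. Of named-gene values under 28 alternatives 7260 kept both, 332 lost the call, 76 gained it and 11 reversed. Of list values under 29 alternatives 2462 kept both, 62 lost the call, 72 gained it and 2 reversed. Among those counted as kept, 66 gene values and 38 list values changed sign without a call in either setting. The mean of the probe sets and all probe sets separately are the same calculation for genes and lists. The comparison of only 2 groups gives no correlation of the drugs. MKI67 with nilotinib vs DMSO reversed to 0.037 with the mean of its 4 probe sets, which disagree (-1.16 to 0.82). The other reversed values arose with median centring. It lowers every log2 fold change by 0.23 (imatinib vs DMSO), 0.52 (nilotinib vs DMSO) or 0.30 (nilotinib vs imatinib), so smaller positive values turn negative by construction. With nilotinib vs DMSO these were TOB2 at -0.00065, BCR at -0.077 and ABL1 at -0.16. With nilotinib vs imatinib they were ABL1 at -0.28, HBZ at -0.30, CAT at -0.11 and HBD at -0.29. With imatinib vs DMSO they were DUT at -0.028 and NDUFB2 at -0.048. For the list of cytosolic ribosomal proteins, camera's direction turned to lower with nilotinib vs DMSO with median centring. Its mean against other genes was -0.11 there and as deposited alike. With nilotinib vs imatinib the list turned to higher with cyclic loess (mean against other genes 0.13). A minimum log2 change of 1 left 587, 1364 and 87 genes by construction. All probe sets separately gave 7395 for nilotinib vs DMSO, by construction, since more are tested. Nilotinib vs imatinib gave 2722 genes with median centring, which lowered every log2 difference by 0.30. It gave 414 without the 4 arrays of high actin ratio, with fewer arrays. Lists passing with an estimated correlation were 7, 8 and 4. With each array left out in turn, genes changed were 2763 to 3281, 4284 to 4666 and 694 to 1052, the lowest of the last without imatinib replicate 6, and lists 10 to 13, 16 and 9 to 15. The correlation of the drugs was 0.869 to 0.894. Genes whose mean log2 value over all arrays lay below 6.59, a signal of 80.6, were left out. Changes of genes dim in every group are therefore not covered. A gene dim in only some of the groups could still pass the filter. On the log2 scale, NFASC lay at 5.10 to 6.52 on the DMSO arrays. RDH8 lay at 5.55 to 6.49 on the imatinib arrays.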

Other observations

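The following genes and families were chosen after their values were seen, and their tests are exploratory, over 113 families of gene symbols per comparison. The cytosolic aminoacyl-tRNA synthetases, formed after WARS1 and the ATF4 list had been seen and overlapping that list, had 14 of 15 members lower with imatinib (median log2 fold change -0.96, adjusted p = 1.48e-12) and 13 of 15 with nilotinib (-1.15, adjusted p = 1.71e-10). The mitochondrial ribosomal protein genes of the large subunit had 13 of 29 lower with imatinib (-0.22, adjusted p = 0.00261, but adjusted p = 0.364 with an estimated correlation) and 23 of 29 with nilotinib (-0.46, adjusted p = 1.05e-06, but adjusted p = 0.125 with an estimated correlation). The cytochrome P450 genes had 11 of 16 higher with nilotinib and none lower (1.06, adjusted p = 0.0349, but adjusted p = 0.349 with an estimated correlation). These medians kept their sign under the 3 other scalings, but not their size. With nilotinib the cytochrome P450 median was 0.54 to 0.63 there, with 6 to 8 of 16 higher, and with median centring the mitochondrial ribosomal protein median was -0.99 with nilotinib (28 of 29 lower) and -0.45 with imatinib, and that of the synthetases -1.68 and -1.19. Of genes called with nilotinib vs DMSO, 84.6% were higher in the lowest of 3 groups by mean signal and 40.1% in the highest. Whether the cytochrome P450 genes rose more than other genes of like signal was not tested.

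Among genes chosen after their values were seen, the quinone reductase gene NQO2, which encodes a known binding protein of imatinib, had a log2 fold change of -1.66 ± 0.10 with imatinib and -1.78 ± 0.10 with nilotinib (SE, n = 4 each). The SRC family kinase gene LYN had -1.01 ± 0.09 and -1.36 ± 0.09. The cell cycle inhibitor gene CDKN1A had -0.95 ± 0.32 with imatinib (adjusted p = 0.0235) and 0.15 ± 0.32 with nilotinib (adjusted p = 0.703), and was 1.10 ± 0.32 higher with nilotinib than with imatinib (adjusted p = 0.0288).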
